A study of Zea mays with 24 samples.

How the data were processed

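RNA was taken from 6 tissues of maize seeds, with 4 libraries per tissue and 24 libraries in all. Per the labels, the plants were wild type of the inbred line B73, grown in a greenhouse at 24 °C by day and 19 °C by night with 16 h of light at 100 W per square metre. The label of SAL replicate 1 gives wild type without the line's name. About 100 mg of tissue is named per sample, and libraries were poly(A)-selected, paired-end and unstranded, prepared with a TruSeq kit, per the labels' protocols. The submitters' processing notes name TopHat2, Bowtie2 and the genome build B73 RefGen_v4. Tool versions, the gene annotation release, the read counter's settings and any trimming are not given in the sources used here.

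The deposited values are whole-number read counts per gene, not normalised, with 1 file per library, per the file contents, whose last 5 rows are the summary rows that htseq-count writes. Those summary rows were kept out of library sizes and tests. Relative to all rows, alignment records not uniquely placed made up 7.81% to 16.2% of a library, records outside any gene 4.24% to 6.41% and records ambiguous between genes 1.07% to 2.63%. A read placed at several positions can give several records, so these are not shares of reads. The rows for unaligned and low-quality reads held 0 in each library, so the share of reads that failed to align is unknown. Because reads placed at several positions were not counted to genes, near-identical copies, such as members of multigene families, lose reads and are uncertain. Without strand information, reads of overlapping genes on opposite strands could not be told apart.

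Each file listed 41614 genes by identifier and 154 microRNA precursor loci by name. The gene table at hand, made for the assembly Zm-B73-REFERENCE-NAM-5.0, holds 49888 genes, and 0 of the 41614 identifiers matched it. Genes are therefore printed by identifier, with at most 2 per direction in a comparison, and no gene of this kind is named. The tests of gene lists fixed before the data were examined could not be run for the same reason, and 0 lists were tested. The fixed rule named genes with an adjusted p under 0.05, at least an 8-fold difference, a mean of at least 20 CPM in the higher tissue and 4 libraries above the other tissue's 4, and otherwise the 2 identifiers per direction with the largest fold. Among microRNA loci, MIR167g alone met that rule in any comparison. All 48 tested microRNA loci are described as well, a choice made after the files had been seen. Their counts are reads of poly(A)-selected precursor transcripts and do not measure the mature small RNA.

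Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with tissue as the group and a minimum count of 10, which left 26543 features, and libraries were scaled by TMM factors. A quasi-likelihood model with tissue as its term was fitted to the 24 libraries together, so that every comparison shared the estimate of spread, and the test was glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method within each comparison. The SE printed with a log2 fold change is the size of that change divided by the square root of the test's F statistic. It is not a standard error from the fit, and no interval should be built from it. A gene was counted as higher or lower where its adjusted p was under 0.05 and its log2 fold change was at least 3 in size, an 8-fold difference. Tissue-enriched genes passed that rule against each of the other 5 tissues. TMM scaling roughly centres the fold changes, so the balance of calls at any fold is largely set by it. The median log2 fold change lay furthest off centre in SAL against End, at 0.239. CPM (library-size-scaled counts, edgeR's cpm) were computed on TMM-scaled library sizes. Counts of genes at 1 CPM or more, and the filter of 1 CPM in 12 libraries, instead used library sizes without TMM factors. Similarity between libraries was the Spearman correlation across genes of log2 CPM with a prior count of 1, and genes are not independent replicates. Single measures per library were compared by exact permutation tests, adjusted over 28 tests.

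Where a tissue held 0 reads of a gene, the fold is a lower bound against 3 reads summed over its 4 libraries, and with 1 to 3 reads the ratio of reads is given with a 95% interval. These bounds and intervals cover counting error only. In single libraries, 3 reads corresponded to between 0.0450 CPM in the deepest library and 0.162 CPM in the shallowest. No pair of libraries within a tissue was identical: the chi-square per degree of freedom between replicates was 7.03 or more. The design text calls the replicates biological, the labels do not say how many plants each pooled, and p-values measure the spread between these samples.

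The labels give replicates with the same number a shared harvest day across tissues: 27 April for number 1, 1 May for number 2, 4 May for number 3 and 18 May for number 4. Exceptions are EAS replicate 3, whose label reads as 5 April, Emb replicate 1, whose year is given as 20 in place of 15, and SAL replicate 4, with no date. The numbers therefore pair the samples. Deviations from the tissue mean correlated at a mean of 0.0891 over 60 pairs with the same number and at -0.0298 over 180 pairs with different numbers. Deviations cancel within a tissue, so the negative mean follows from the positive one and is no further evidence of pairing. The fit without a term for the replicate number was the main design, and the fit with it as a block was an alternative.

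Other alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper quartile factors, no low-count filter, a filter of 1 CPM in at least 12 libraries, edgeR's legacy quasi-likelihood, a fit to the libraries of the compared tissues alone, and leaving out each replicate in turn. Leaving out the 3 libraries with deviating date labels, and the shallowest library in every fit, were added after the data had been seen. The main test was tested on simulated counts for 26543 genes, with the EAS libraries given the End means apart from the changed genes. Changed genes were drawn from those with at least 1 CPM in End, so the rates do not cover genes at lower levels. Far fewer genes were changed than the 16511 called between the real EAS and End libraries. The filter kept 26239 simulated genes, so some unchanged genes could not be called. The test called 100% of 100 genes changed 4-fold and 100% of 100 genes changed 16-fold, and 9 of 26343 unchanged genes. At the 8-fold rule it called 0% of the genes changed 4-fold, 100% of those changed 16-fold and 0 unchanged genes.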

Results

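The transcriptomes of 6 dissected parts of the maize seed were compared: embryo (Emb), apical scutellum (AS), endosperm (End), endosperm adjacent to the scutellum (EAS), scutellar aleurone layer (SAL) and pericarp (Per), each with 4 libraries. The embryo and the endosperm, a starch-storing tissue, arise from fertilisation, the pericarp is maternal fruit wall, and the scutellum is the part of the embryo that faces the endosperm. The series title names signalling between seed compartments as its subject, and its design text names a comparison of organs. Reads counted in genes averaged 49.7 M ± 8.25 in Emb, 48.1 M ± 0.673 in AS, 47.0 M ± 4.34 in End, 49.2 M ± 3.11 in EAS, 39.7 M ± 16.9 in SAL and 42.7 M ± 6.49 in Per (SD, n = 4). The shallowest library was SAL replicate 2 with 15.1 M reads, every other library held at least 37.6 M, and the deepest was Emb replicate 2 with 61.1 M. The labels do not say whether the Emb samples contained AS tissue, or the End samples EAS and SAL tissue, so differences of AS, EAS and SAL from these are differences from samples of unknown overlap. Features called 8-fold higher or lower had an edgeR adjusted p under 0.05 and a fitted fold change of 8 or more, which is not a lower bound: with 3 reads or fewer in the lower tissue, counting error leaves smaller folds possible. Levels below are mean CPM ± SD over the 4 libraries of a tissue. The SE of a log2 fold change was derived from the F statistic and is not a fitted standard error. MicroRNA loci, named MIR, are measured by reads of their polyadenylated precursor transcripts.

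The embryo and the apical scutellum were the most similar pair of tissues, with a mean Spearman correlation across genes of 0.975, followed by endosperm and EAS at 0.947, endosperm and SAL at 0.913, and SAL and pericarp at 0.902. EAS and SAL correlated at 0.873, and the embryo correlated with pericarp at 0.759. Libraries of the same tissue correlated at 0.988 or more. In a principal component plot, the first component, with 54.1% of the variance, separated Emb and AS from the remaining tissues, and the second, with 26.3%, ordered EAS, End, SAL and Per. At 1 CPM or more in each of the 4 libraries, 20709 genes were detected in SAL, 20706 in Per, 19477 in Emb, 18864 in AS, 18340 in End and 17794 in EAS. Of 23244 genes that met this rule in at least 1 tissue, 15602 met it in all 6 tissues, and 734 met it in pericarp without meeting it in another tissue.

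**Figure D1:**
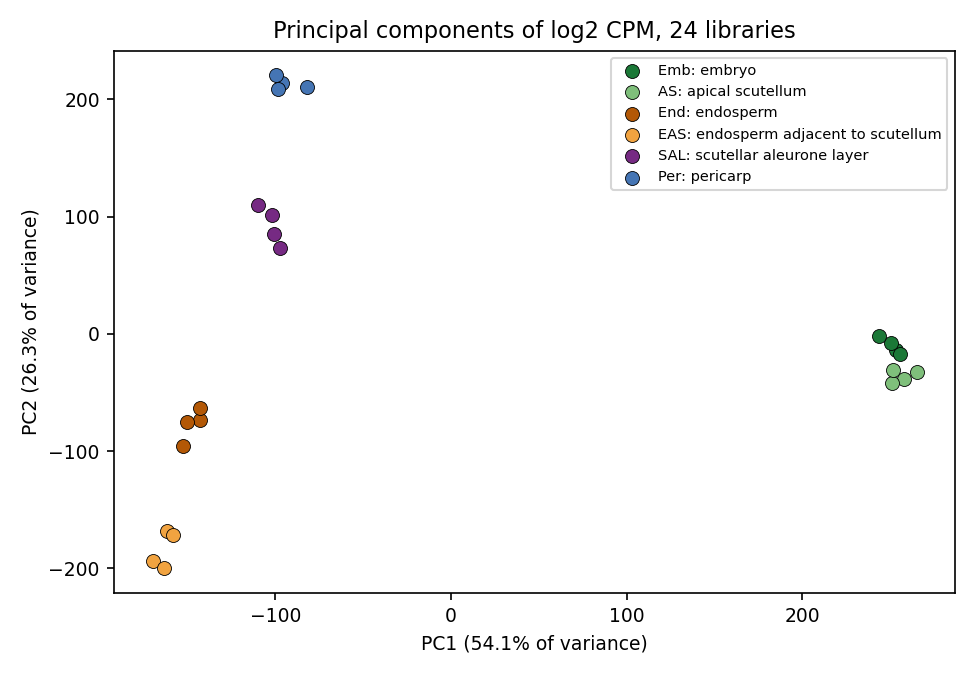
Each point is 1 of the 24 libraries, placed by its first principal component (54.1% of the variance) and second (26.3%) of log2 CPM over the tested genes; colours mark the 6 tissues. Emb and AS libraries lie together at the right, and SAL lies between End and Per on the second component.

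Reads were concentrated on few transcripts in the endosperm tissues. The 10 most abundant genes of a library took 15.1% ± 0.780 of its gene reads in End, 9.32% ± 0.865 in EAS, 5.79% ± 0.181 in SAL, 4.41% ± 0.372 in AS, 3.62% ± 0.0554 in Emb and 3.38% ± 0.265 in Per. The share of alignment records without a unique position was also highest in End, at 15.0% ± 1.01, then in EAS at 12.5% ± 0.939 and SAL at 11.2% ± 0.534. The remaining tissues came in the reverse order, with 8.55% ± 0.252 in Per, 8.34% ± 0.241 in Emb and 7.98% ± 0.181 in AS. Both measures were higher in End than in EAS, SAL, Emb and Per, each with an exact permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and 0.0364 after adjustment over 28 tests.

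**Figure D2:**
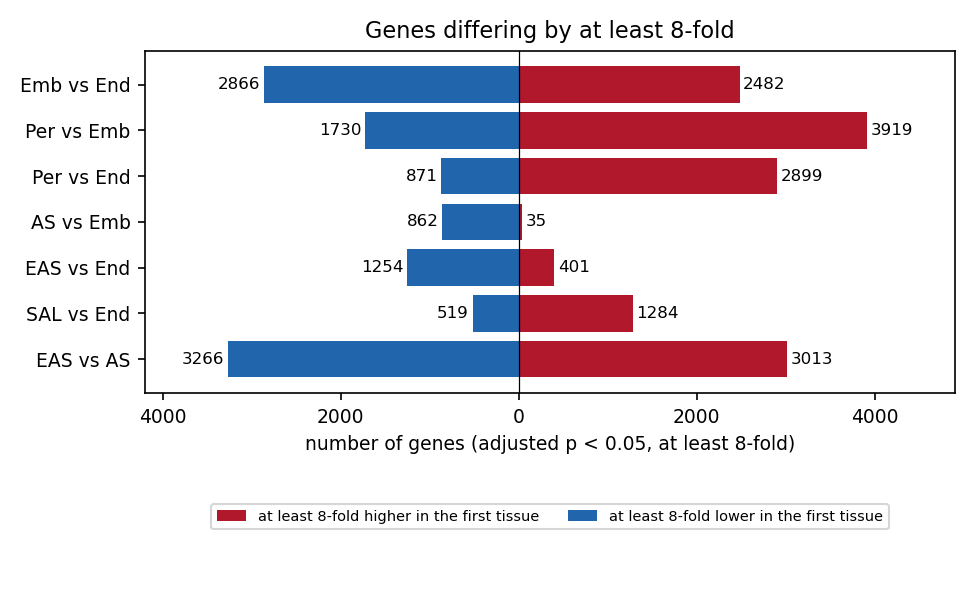
Bars give the number of genes called 8-fold higher (to the right) or lower (to the left) in the first-named tissue of each of the 7 comparisons, from edgeR at an adjusted p under 0.05; the printed values are the counts. AS and Emb differed least, with 35 and 862 genes, and EAS and AS most, with 3013 and 3266.

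Embryo and endosperm, the 2 products of fertilisation, kept different microRNA precursors. Of the 48 tested loci, 22 were called 8-fold higher in the embryo and 6 called 8-fold higher in the endosperm, and 10 had no call. With 0 reads in the lower tissue, the bounds were below 8 for MIR164g (at least 6.25-fold) and MIR166a (at least 5.39-fold) among the embryo-high loci, and for MIR167j (at least 7.74-fold) and MIR172e (at least 7.22-fold) among the endosperm-high loci. The call of MIR399j, counted among the 22, was lost without Emb replicate 1 or 2 and without each End replicate in turn (edgeR adjusted p from 0.0548 to 0.0915). Among the embryo-high ones were 6 of the 7 tested MIR156 loci, whose microRNA targets SPL transcription factors. MIR156e reached 9.16 ± 1.25 CPM in Emb with 0 reads in End (at least 432-fold higher, edgeR adjusted p = 1.45e-17). MIR156b reached 5.49 ± 0.942 CPM with 0 reads in End (at least 260.5-fold, edgeR adjusted p = 5.2e-11). MIR156j went the other way, at 0.0388 ± 0.0193 CPM in Emb and 0.647 ± 0.112 in End (log2 fold change -4.05, SE 0.46, edgeR adjusted p = 1.43e-08). MIR159a, of a family that targets GAMYB transcription factors, was at 7.44 ± 0.402 CPM against 0.0802 ± 0.0509 (log2 fold change 6.53, SE 0.24, edgeR adjusted p = 2.01e-17). MIR166d, of the family that targets class III HD-ZIP regulators, was at 6.10 ± 0.940 against 0.238 ± 0.151 CPM (log2 fold change 4.65, SE 0.30, edgeR adjusted p = 1.29e-12). MIR160d at 1.82 ± 0.329 CPM, MIR390a at 2.60 ± 0.646 and MIR319d at 2.07 ± 0.166 in Emb each had 0 reads in End, which bounds their folds as at least 85.3-fold, at least 124-fold and at least 97.4-fold. These families act on auxin response factors, on the TAS3 pathway and on TCP factors, in that order. Of 4 precursors of microRNAs linked to copper proteins, 3 were embryo-high as well: MIR408b with 3.03 ± 0.960 against 0.0815 ± 0.0956 CPM, MIR528a with 2.85 ± 0.745 against 0.0336 ± 0.0307, and MIR398a with 1.78 ± 0.311 against 0.0288 ± 0.0251. The other, MIR398b, had 2.82 ± 0.605 CPM in Emb and 2.74 ± 0.926 in End and was not called (log2 fold change 0.05, SE 0.36, edgeR adjusted p = 0.898). The endosperm's most abundant precursor was MIR167g, of the family that targets the auxin response factors ARF6 and ARF8, with 56.9 ± 4.98 CPM against 5.94 ± 1.34 in Emb (log2 fold change -3.26, SE 0.26, edgeR adjusted p = 9.22e-11). Its relative MIR167a had similar levels in both tissues, 5.41 ± 1.33 CPM in Emb and 4.91 ± 1.64 in End, and was not called.

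Over all 26543 tested features, 2482 were called 8-fold higher in the embryo and 2866 called 8-fold higher in the endosperm, and 21852 differed at any fold. Under the fixed rule, Zm00001d053594 had 63.1 ± 3.80 CPM in Emb and 0 reads in End (at least 2952-fold higher). Zm00001d025136 had 59.9 ± 5.19 CPM in Emb and 0 reads in End (at least 2824-fold). In the other direction, Zm00001d029879 had 85.3 ± 8.53 CPM in End and 0 reads in Emb (at least 6156-fold). Zm00001d032095 had 204 ± 15.0 CPM in End with 1 read in Emb, a ratio of 44744 with a 95% counting interval of 8030.1 to 1767360. Both 8-fold counts were larger than any other split of the same 8 libraries gave, but every other split mixes the tissues, which widens the spread within groups. The splits thus show that the tissues differ and do not gauge the size of the counts. Both counts fell to 1101 and 1323 when genes needed 1 CPM in 12 libraries. That filter removes genes of single tissues and also genes shared by Emb and AS alone or by End and EAS alone.

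**Figure D3:**
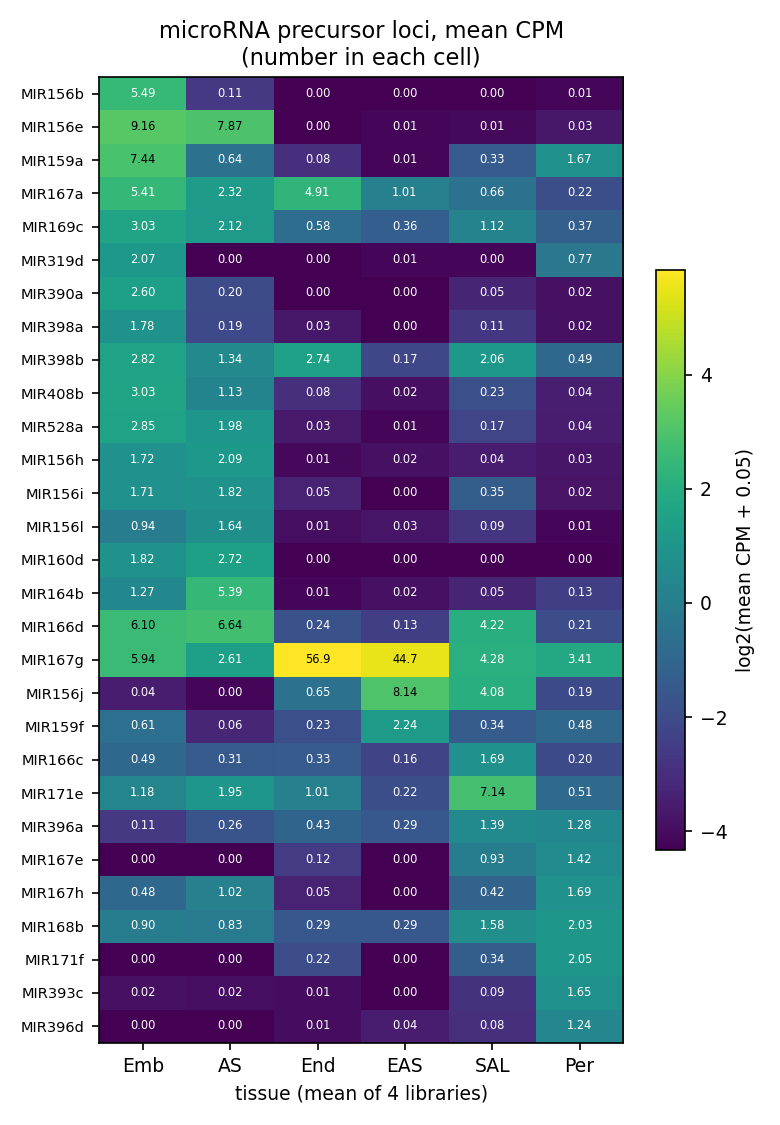
Cells give the mean CPM (4 libraries per tissue) of the 29 microRNA precursor loci with a mean of at least 1 CPM in some tissue, ordered by the tissue with the highest mean; the colour scale is log2 of the mean plus 0.05. MIR167g stands highest, at 56.9 CPM in End and 44.7 in EAS, while the MIR156 loci other than MIR156j are high in Emb, most of them in AS too.

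The maternal pericarp and the embryo differed in nearly all tested microRNA loci: 10 were called 8-fold higher in pericarp, 21 called 8-fold higher in the embryo, and 2 had no call. Of these, MIR172e had 0 reads in Emb and a bound of at least 7.05-fold, and the call of MIR399j was lost without Emb replicate 2 (edgeR adjusted p = 0.0618). MIR171f, of a family that targets GRAS-domain regulators, had 2.05 ± 0.263 CPM in Per and 0 reads in Emb (at least 148-fold higher, edgeR adjusted p = 3.75e-10). All 3 tested MIR396 loci, whose microRNA targets growth-regulating factors, were called 8-fold higher in pericarp. MIR396d reached 1.24 ± 0.236 CPM with 0 reads in Emb (at least 90.5-fold, edgeR adjusted p = 3.98e-14). MIR396a reached 1.28 ± 0.234 against 0.112 ± 0.0234 CPM (log2 fold change 3.49, SE 0.25, edgeR adjusted p = 1.27e-11). MIR393c, of the family that targets the auxin receptors, was at 1.65 ± 0.618 CPM in Per and 0.0180 ± 0.0151 in Emb (log2 fold change 6.30, SE 0.45, edgeR adjusted p = 1.16e-14). Within the MIR167 family the loci split: MIR167e had 1.42 ± 0.0919 CPM in Per and 0 reads in Emb (at least 104-fold). MIR167a had 0.220 ± 0.226 in Per and 5.41 ± 1.33 in Emb (log2 fold change -4.67, SE 0.48, edgeR adjusted p = 5.87e-09). In pericarp, 6 of the 7 MIR156 loci were called 8-fold lower, among them MIR156e at 0.0285 ± 0.0435 CPM (log2 fold change -8.34, SE 0.33, edgeR adjusted p = 4.74e-18). MIR164b, of the family that targets NAC genes of organ boundaries, was also lower, 0.132 ± 0.0533 against 1.27 ± 0.109 CPM (log2 fold change -3.29, SE 0.29, edgeR adjusted p = 1.1e-11).

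In total, 3919 features were called 8-fold higher in pericarp and 1730 called 8-fold higher in the embryo, and 22254 of the 26543 tested differed at any fold. Among features that met the fixed rule, the largest fitted folds toward pericarp were those of Zm00001d047621, with 119.5 ± 38.9 CPM in Per and 0 reads in Emb (at least 8555-fold higher), and Zm00001d042591, with 68.3 ± 9.10 CPM and 0 reads in Emb (at least 4913-fold). Toward the embryo they were those of Zm00001d018876, with 36.3 ± 5.11 CPM in Emb and 0 reads in Per (at least 2352-fold), and Zm00001d034413, with 188 ± 40.1 against 0.0335 ± 0.0423 CPM (log2 fold change -12.46, SE 0.50, edgeR adjusted p = 8.78e-21). The counts were 1656 and 770 with the filter of 1 CPM in 12 libraries.

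Pericarp against endosperm showed 11 microRNA loci called 8-fold higher in pericarp and 3 called 8-fold higher in endosperm, with 21 of the 48 not called. The 3 endosperm-high loci all belonged to the MIR167 family: MIR167g (3.41 ± 0.839 CPM in Per, log2 fold change -4.07, SE 0.28, edgeR adjusted p = 4.81e-12), MIR167a (0.220 ± 0.226 against 4.91 ± 1.64 CPM, log2 fold change -4.52, SE 0.50, edgeR adjusted p = 1.68e-08) and MIR167d (0.0606 ± 0.00982 against 0.584 ± 0.130 CPM, log2 fold change -3.19, SE 0.42, edgeR adjusted p = 2.36e-07). In the same family, 2 loci were called 8-fold higher in pericarp, MIR167h with 1.69 ± 0.136 against 0.0480 ± 0.0329 CPM (log2 fold change 5.01, SE 0.39, edgeR adjusted p = 8.14e-11) and MIR167e with 1.42 ± 0.0919 against 0.121 ± 0.0262 (log2 fold change 3.54, SE 0.22, edgeR adjusted p = 2.09e-09). MIR159a was higher in pericarp at 1.67 ± 0.217 against 0.0802 ± 0.0509 CPM (log2 fold change 4.38, SE 0.29, edgeR adjusted p = 1.22e-12). MIR319d had 0.773 ± 0.166 CPM in Per with 0 reads in End (at least 36.7-fold). MIR168a, whose microRNA targets the ARGONAUTE1 transcript, was at 0.465 ± 0.0993 against 0.0423 ± 0.0286 CPM (log2 fold change 3.34, SE 0.51, edgeR adjusted p = 7.18e-07). Across all features, 2899 were called 8-fold higher in pericarp and 871 called 8-fold higher in endosperm, and 21651 differed at any fold. Under the rule, Zm00001d022630 had 44.6 ± 27.6 CPM in Per and 1 read in End, a ratio of 6401 with a 95% counting interval of 1149 to 252856, and Zm00001d048083 had 148 ± 19.2 against 0.0447 ± 0.0710 CPM (log2 fold change 11.47, SE 0.41, edgeR adjusted p = 4.24e-21). Toward the endosperm, Zm00001d042875 had 48.7 ± 6.05 against 0.365 ± 0.0715 CPM (log2 fold change -7.06, SE 0.37, edgeR adjusted p = 1.2e-11). Zm00001d044129 had 6447 ± 553 against 86.8 ± 40.8 CPM (log2 fold change -6.22, SE 0.38, edgeR adjusted p = 5.53e-13). The count of 871 was 1309 without a low-count filter and 376 with the filter of 1 CPM in 12 libraries.

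The apical scutellum, the tip of the embryo's storage and transfer organ, was compared with Emb. In AS, 862 features were called 8-fold lower and 35 called 8-fold higher, and of 10260 calls at any fold 5082 were higher and 5178 lower, a balance that the scaling itself largely sets. No microRNA locus was called 8-fold higher in AS by edgeR, with 0 also at an unadjusted p under 0.05 and 0 by DESeq2, and 9 were called 8-fold lower. MIR319d fell from 2.07 ± 0.166 CPM in Emb to 0 reads in AS (at least 137-fold lower, edgeR adjusted p = 3.29e-10). MIR319a fell from 0.403 ± 0.125 CPM to 0 reads (at least 26.4-fold, edgeR adjusted p = 4.66e-05). MIR156b fell to 0.111 ± 0.0259 CPM (log2 fold change -5.60, SE 0.26, edgeR adjusted p = 1e-09), MIR390a to 0.201 ± 0.146 (log2 fold change -3.68, SE 0.33, edgeR adjusted p = 8.47e-09) and MIR159a to 0.644 ± 0.105 (log2 fold change -3.53, SE 0.16, edgeR adjusted p = 1.56e-14). MIR156e, by contrast, was at 7.87 ± 0.439 CPM in AS and 9.16 ± 1.25 in Emb and was not called. Both tested MIR164 loci were higher in AS, MIR164b at 5.39 ± 1.11 against 1.27 ± 0.109 CPM (log2 fold change 2.08, SE 0.17, edgeR adjusted p = 3.57e-11) and MIR164g at 0.447 ± 0.0963 against 0.129 ± 0.0522 (log2 fold change 1.74, SE 0.33, edgeR adjusted p = 0.000838). MIR160d was also higher in AS, at 2.72 ± 0.162 CPM (log2 fold change 0.58, SE 0.16, edgeR adjusted p = 0.0137). MIR160b was lower, at 0.110 ± 0.0504 against 0.403 ± 0.0629 CPM (log2 fold change -1.83, SE 0.37, edgeR adjusted p = 0.000184).

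Of the 862 AS-low features, 343 had their highest mean in the embryo and 281 in the pericarp among the 6 tissues. Of the 35 AS-high features, 16 were highest in Per, 9 in SAL, 5 in AS, 3 in EAS and 2 in End. Their median level was between 0.0995 CPM in AS replicate 2 and 0.422 CPM in AS replicate 3, against at most 0.0414 CPM in the Emb libraries. Among them, Zm00001d002410 had 25.0 ± 10.8 CPM in AS and 2.72 ± 1.49 in Emb (log2 fold change 3.18, SE 0.52, edgeR adjusted p = 3.76e-05). Zm00001d034145 had 25.2 ± 14.3 against 2.94 ± 1.57 CPM (log2 fold change 3.10, SE 0.46, edgeR adjusted p = 1.04e-05). Among the AS-low features, Zm00001d011342 had 0.141 ± 0.113 against 61.2 ± 11.6 CPM in Emb (log2 fold change -8.74, SE 0.59, edgeR adjusted p = 6.46e-11). Zm00001d026329 had 0.206 ± 0.151 against 62.1 ± 8.0 CPM (log2 fold change -8.22, SE 0.30, edgeR adjusted p = 1.55e-15). The count of 35 rested on single libraries: it was 77 without Emb replicate 3, 66 without AS replicate 2, 21 without Emb replicate 2, and 22 without AS replicate 3 or without AS replicate 4. It was 64 by DESeq2, 57 without a low-count filter, 12 with the filter of 1 CPM in 12 libraries and 14 when only AS and Emb were fitted.

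In the endosperm next to the scutellum, 1254 features were called 8-fold lower than in End and 401 called 8-fold higher. At any fold, 16511 were called, 8012 higher and 8499 lower in EAS. Of the microRNA loci, 2 were called 8-fold higher in EAS. MIR156j rose to 8.14 ± 1.53 CPM from 0.647 ± 0.112 in End (log2 fold change 3.64, SE 0.21, edgeR adjusted p = 6.06e-13). MIR159f rose to 2.24 ± 0.375 from 0.227 ± 0.0242 (log2 fold change 3.29, SE 0.25, edgeR adjusted p = 8.31e-11). Another 8 loci were called 8-fold lower, among them MIR398b at 0.173 ± 0.103 against 2.74 ± 0.926 CPM (log2 fold change -3.97, SE 0.58, edgeR adjusted p = 3.12e-06), whose microRNA targets copper/zinc superoxide dismutases. MIR171f fell from 0.216 ± 0.0842 CPM to 0 reads (at least 11.9-fold lower). The bounds of 5 others with 0 reads in EAS were below 8: MIR167e (at least 6.76-fold), MIR172e (at least 5.57-fold), MIR156i (at least 2.78-fold), MIR167h (at least 2.78-fold) and MIR398a (at least 1.59-fold). The call of MIR398a was lost by DESeq2 (log2 fold change -2.74, adjusted p = 0.053), without a low-count filter (edgeR adjusted p = 0.0684), without each EAS replicate in turn and without End replicate 2, 3 or 4 (edgeR adjusted p from 0.0681 to 0.128). MIR167a was lower in EAS, at 1.01 ± 0.479 CPM (log2 fold change -2.27, SE 0.39, edgeR adjusted p = 2.86e-05), while MIR167g remained at 44.7 ± 5.75 against 56.9 ± 4.98 CPM and was not called. Of the 401 EAS-high features, 257 had their highest mean in EAS, 47 in Per, 45 in SAL, 32 in Emb and 20 in AS. Of the 1254 EAS-low features, 570 were highest in Per and 294 in SAL, and 109 in End. Zm00001d025399 had 33.4 ± 11.2 CPM in EAS and 1.74 ± 0.563 in End (log2 fold change 4.24, SE 0.35, edgeR adjusted p = 1.14e-10). Zm00001d040593 had 298 ± 76.1 against 16.6 ± 2.11 CPM (log2 fold change 4.17, SE 0.28, edgeR adjusted p = 2.69e-11). In the other direction, Zm00001d051110 had 0.0895 ± 0.0307 CPM in EAS and 42.3 ± 11.9 in End (log2 fold change -8.85, SE 0.36, edgeR adjusted p = 1.09e-15). Zm00001d005146 had 0.287 ± 0.102 against 94.0 ± 22.6 CPM (log2 fold change -8.35, SE 0.37, edgeR adjusted p = 4.17e-14). The count of 1254 was 825 when only EAS and End were fitted, and the counts were 123 and 636 with the filter of 1 CPM in 12 libraries.

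The scutellar aleurone layer had more transcripts higher than lower against the endosperm: 1284 features were called 8-fold higher in SAL and 519 called 8-fold lower. At any fold, 20307 were called, 12024 higher and 8283 lower. The median log2 fold change of all tested features was 0.239, and 0.0355 when only SAL and End were fitted. Part of the balance, also among the microRNA loci, thus depends on the scaling and the features kept. Of the 48 microRNA loci, 27 were higher in SAL at some fold, 7 of them called 8-fold higher, and 5 were lower. Among the 7, MIR171d and MIR390a had 0 reads in End and bounds of at least 3.21-fold. The call of MIR390a was lost without SAL replicate 3, End replicate 2 or End replicate 4 (edgeR adjusted p = 0.126, 0.0505 and 0.0545). MIR166d reached 4.22 ± 0.809 CPM against 0.238 ± 0.151 in End (log2 fold change 4.13, SE 0.31, edgeR adjusted p = 4.04e-11). MIR171e reached 7.14 ± 1.39 against 1.01 ± 0.312 (log2 fold change 2.78, SE 0.24, edgeR adjusted p = 3.82e-10). MIR156j was at 4.08 ± 0.801 against 0.647 ± 0.112 CPM (log2 fold change 2.62, SE 0.22, edgeR adjusted p = 9.7e-11). MIR172e, of the family that targets APETALA2-type regulators, was at 0.863 ± 0.239 against 0.0966 ± 0.0956 CPM (log2 fold change 3.06, SE 0.47, edgeR adjusted p = 3.56e-05). MIR168a was at 0.506 ± 0.0974 against 0.0423 ± 0.0286 (log2 fold change 3.48, SE 0.51, edgeR adjusted p = 3.46e-07). MIR396a was at 1.39 ± 0.214 CPM in SAL (log2 fold change 1.69, SE 0.21, edgeR adjusted p = 2.25e-07), with 1.28 ± 0.234 in Per, and pericarp markers as a set stood at a median of 14.4% of their pericarp level in SAL and 4.07% in End. Those markers were chosen to be 8-fold lower in End and were not chosen on SAL, so the shares are not like for like. MIR167g was at 4.28 ± 1.82 CPM in SAL (log2 fold change -3.78, SE 0.28, edgeR adjusted p = 2.87e-11) and MIR167a at 0.663 ± 0.410 (log2 fold change -3.06, SE 0.43, edgeR adjusted p = 9.73e-07), both lower than in End.

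Of the 1284 SAL-high features, 509 had their highest mean in SAL, 415 in Per, 192 in Emb, 147 in AS and 21 in EAS. Of the 519 SAL-low features, 381 were highest in End. Zm00001d033522 had 60.6 ± 8.92 CPM in SAL and 0.213 ± 0.144 in End (log2 fold change 8.14, SE 0.44, edgeR adjusted p = 1.6e-13). Zm00001d047559 had 37.2 ± 5.24 against 0.212 ± 0.118 CPM (log2 fold change 7.39, SE 0.35, edgeR adjusted p = 2.07e-14). Zm00001d042875 had 0.412 ± 0.155 against 48.7 ± 6.05 CPM (log2 fold change -6.88, SE 0.37, edgeR adjusted p = 3.09e-11). Zm00001d047066 had 0.263 ± 0.0890 against 30.6 ± 9.90 CPM (log2 fold change -6.85, SE 0.41, edgeR adjusted p = 8.23e-13). The count of 1284 was 808 when only SAL and End were fitted, and the counts were 367 and 267 with the filter of 1 CPM in 12 libraries.

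EAS and AS face each other across the boundary between endosperm and embryo. In EAS, 3013 features were called 8-fold higher and 3266 called 8-fold lower than in AS, and 21878 differed at any fold. Of the microRNA loci, 5 were called 8-fold higher in EAS and 20 called 8-fold lower. With 0 reads in the lower tissue, bounds were below 8 for MIR396d (at least 2.36-fold) and MIR156b (at least 6.21-fold). MIR156j and MIR156e, of the same family, stood on opposite sides: MIR156j had 8.14 ± 1.53 CPM in EAS and 1 read in AS, a ratio of 1615 with a 95% counting interval of 289 to 63845, and MIR156e had 7.87 ± 0.439 CPM in AS and 1 read in EAS, a ratio of 1324 with a 95% counting interval of 237 to 52347. MIR167g was at 44.7 ± 5.75 CPM in EAS and 2.61 ± 0.901 in AS (log2 fold change 4.10, SE 0.28, edgeR adjusted p = 4.15e-12), and MIR159f at 2.24 ± 0.375 against 0.0553 ± 0.0188 (log2 fold change 5.27, SE 0.29, edgeR adjusted p = 4.36e-14). MIR160d, at 2.72 ± 0.162 CPM in AS, had 0 reads in EAS (at least 152-fold lower, edgeR adjusted p = 4.47e-09), and MIR156i, at 1.82 ± 0.196 CPM, had 0 reads as well (at least 102-fold). MIR164b had 3 reads in EAS, a ratio of 302 with a 95% counting interval of 103 to 1466. MIR166d was at 0.134 ± 0.0972 CPM in EAS against 6.64 ± 1.58 in AS (log2 fold change -5.58, SE 0.31, edgeR adjusted p = 1.02e-13). Of features known by identifier, Zm00001d043276 had 46.0 ± 12.8 CPM in EAS and Zm00001d007263 had 43.5 ± 6.95 CPM, each with 0 reads in AS (at least 3015-fold and at least 2882-fold higher). Zm00001d029446 had 81.7 ± 6.35 CPM in AS and 0 reads in EAS (at least 4579-fold lower). Zm00001d036917 had 324 ± 16.4 CPM in AS and 2 reads in EAS, a ratio of 27228 with a 95% counting interval of 7537 to 224837. Between EAS and Emb the total was 6274 features, against 6279 between EAS and AS, and with the filter of 1 CPM in 12 libraries the counts for EAS against AS were 1388 and 1913.

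Genes called 8-fold higher than in each of the other 5 tissues were most numerous in the pericarp, with 642, followed by the embryo with 192, EAS with 85, SAL with 75 and the endosperm with 31. The apical scutellum had 0 by edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2, and 3 without a low-count filter. Each set can be no larger than the 8-fold calls of its tissue over any single other tissue. The sizes did not follow the correlation with the nearest tissue. Emb, at 0.975 with AS, had 192 genes, while End and EAS, at 0.947 with each other, had 31 and 85. AS could hold no more than the 35 features called 8-fold above Emb in the main fit, and the Emb samples may have contained AS tissue. End had to exceed EAS, with which it correlated at 0.947, while the tissue nearest to Per was SAL, at 0.902. MicroRNA loci belonged to 3 of these sets. The embryo set held MIR156b, MIR319a, MIR390a and MIR398a, the pericarp set held MIR393c and MIR396d, and the SAL set held MIR172e. Median levels in the enriched tissue were low, from 2.30 CPM in SAL and 2.53 in Emb to 6.38 in End, and 178 of the 642 pericarp genes had a mean of at least 20 CPM. Without a low-count filter the endosperm set held 58 genes and the SAL set 115. The order below the pericarp depended on the filter: with 1 CPM required in 12 libraries the sets held 107 genes in Per, 23 in EAS, 8 in End, 7 in Emb and 3 in SAL.

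Genes chosen as markers on Emb, End and Per alone, by an 8-fold excess over both other compartments and a mean of at least 20 CPM, were followed into AS, EAS and SAL. The 425 embryo markers were present in AS at a median of 101% of their embryo level, in SAL at 8.56% and in EAS at 1.55%. The 205 endosperm markers stood at a median of 66.4% in EAS, 8.71% in SAL and 0.118% in AS. Their summed level was 348563 ± 36498 CPM in End, 193831 ± 40172 in EAS and 24325 ± 4762 in SAL (SD, n = 4). The 469 pericarp markers stood at a median of 14.4% in SAL, with single SAL libraries between 10.2% and 18.8%, at 0.852% in AS and at 0.662% in EAS. Low levels were present outside SAL too: End held a median of 4.07% of the pericarp and 3.99% of the embryo marker levels, and Per held 6.69% of the endosperm and 3.07% of the embryo marker levels. The markers were chosen to be low in these compartments, so such levels are held down by the choice. They give no background for AS, EAS or SAL.

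**Figure D4:**
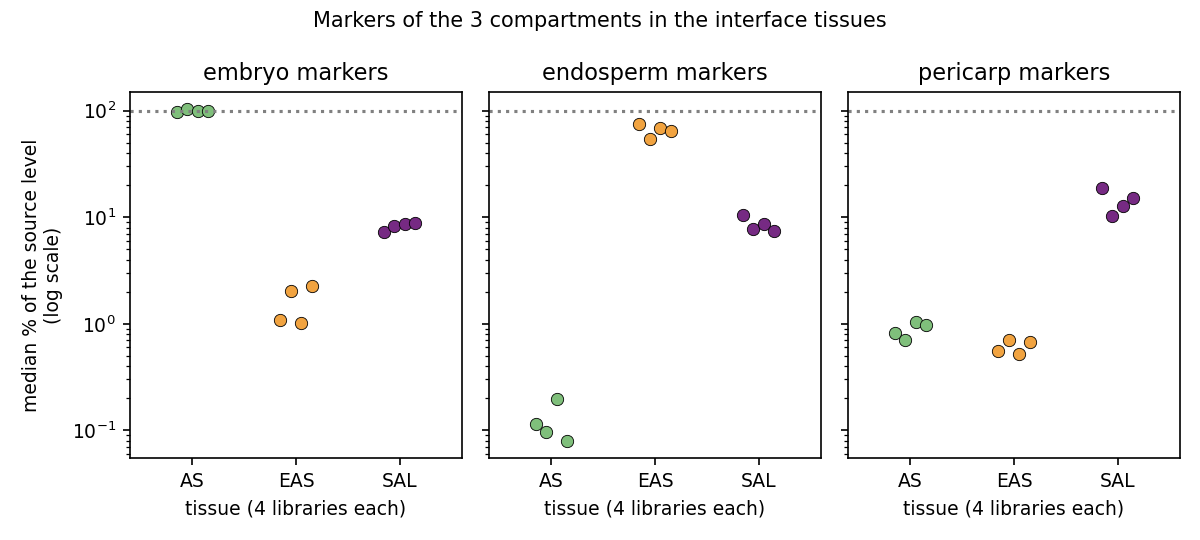
Each point is 1 library of AS, EAS or SAL, and its height on a log axis is the median level of the 425 embryo, 205 endosperm or 469 pericarp markers in percent of their level in the source tissue (dotted line, 100%). Embryo markers in AS lie at the line, and endosperm markers in EAS at a median of 66.4%.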

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

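The splits of libraries and the tests of RNA carried over from another tissue were written before their outcomes were computed, and only the counts of genes within the range of a source's markers, and of regroupings under any tissue name, were chosen after the result was seen.

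Among 172 sets of 4 libraries examined, 10 had a library far from the other 3, against 8.6 that chance alone would give. End replicate 1 had 18709 genes at 1 CPM or more, against 19054 to 19122 in the other End libraries. MIR167a reached 7.34 CPM in End replicate 3, against 3.78 to 4.32 in the others. MIR390a was at 1.64 CPM in Emb replicate 1 (others 2.79 to 2.99) and at 0.418 CPM in AS replicate 2 (others 0.100 to 0.143). In Emb replicate 4, MIR156h was at 2.25 CPM (others 1.48 to 1.59) and MIR160b at 0.496 CPM (others 0.360 to 0.382), and in Emb replicate 2 MIR171e was at 1.57 CPM (others 1.00 to 1.08). In Per replicate 4, MIR159f was at 0.617 CPM (others 0.429 to 0.446) and MIR167j at 0.507 CPM (others 0.380 to 0.391), and in Per replicate 3 MIR2118c was at 0.386 CPM (others 0.253 to 0.265). Outside the gene counts, 15.0% of the endosperm's alignment records were not uniquely placed, a share that entered no comparison of genes.

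The 35 features called 8-fold higher in AS than in Emb were at low levels, and their highest mean lay in the pericarp in 16 cases and in SAL in 9. They needed a median of 28.0% of the pericarp level, while the 469 pericarp markers stood at a median of 0.852% and a 90th percentile of 10.6% in AS; since they were picked for being high in AS and lay near the floor, with a median of 0.0995 CPM in AS replicate 2 against 1.54 to 2.69 CPM in the Per libraries, pericarp RNA was not excluded as their source. For endosperm RNA 296% was needed, against a 90th percentile of 5.84% among the 205 endosperm markers, and for the same reasons it was not excluded either. For 8 genes within the range of the pericarp markers and 3 within that of the endosperm markers, carried-over RNA and expression in AS cannot be told apart, because the markers themselves vary that much and 4 libraries are too few to follow the share. Chance was not excluded for this count, since 2 of the 35 splits of the 8 libraries, the real one included, gave as many. The highest other was 43, with Emb replicate 3 beside AS replicates 1, 3 and 4. For splits other than the real one the larger of the 2 directions was taken, which makes a count as large easier to reach. Among the 8 splits that part every same-day pair the highest other was 1, and a mixture of sources and a difference of the tissues were not tested.

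The 401 features called 8-fold higher in EAS than in End were highest in EAS in 257 cases. RNA from the apical scutellum was argued against, since they needed a median of 7362% of the AS level, against a 90th percentile of 12% among 374 embryo markers in EAS, and 358 of them needed more than the level of AS itself. Pericarp RNA was argued against with a median need of 806%, against a 90th percentile of 11.7%. Carried-over RNA and expression in EAS cannot be told apart for 15 genes within the range of the scutellum source and 14 within that of the pericarp, for want of libraries to follow the share. RNA from SAL, where 45 of the 401 had their highest mean, was not weighed as a source. Nor was RNA from Emb, where 32 had theirs. With apical scutellum and pericarp set aside for the remainder, and SAL and Emb not weighed, expression in the endosperm cells at the scutellum is a hypothesis that fits the labels. That hypothesis was found and examined on the same data and was not itself tested.

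The 1284 features called 8-fold higher in SAL than in End lay beside pericarp markers at 14.4% and embryo markers at 8.56% of their source levels. Pericarp RNA as the source of all of them was argued against by a median need of 177%, against a 90th percentile of 37.4% among the markers, and embryo RNA by a median need of 346%, against 28.5%. However, 332 genes lay within the range of the pericarp markers and 225 within that of the embryo markers, and for these carried-over RNA and expression in SAL cannot be told apart, since SAL, Per and Emb share no independent measure of dissection. For the 509 features with their highest mean in SAL, the level in SAL was above that of either source. A difference between the tissues is the biological explanation the design names, and it remains a hypothesis for them.

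In the comparisons below, no split of the 8 libraries other than the real one reached the count. Other splits have no direction of their own, so for the 8-fold counts the larger of their 2 directions was taken. Every other split also mixes the compared tissues, which widens the spread within its groups and lowers its count. The splits therefore show that the tissues differ and do not gauge the size of the counts. For Emb against End, 1 of 35 splits, the real one, reached 2482 and 2866 features (highest other 1 for both) and 21852 calls (highest other 2). For Per against Emb, with 3919, 1730 and 22254, the highest others were 0, 0 and 1, and for Per against End, with 2899, 871 and 21651, they were 12, 12 and 309. The 862 AS-low features and 10260 calls of AS against Emb stood against highest others of 43 and 2693, the latter from the same split that put Emb replicate 3 with AS. For EAS against End, with 401, 1254 and 16511, the highest others were 34, 34 and 812, and for SAL against End, with 1284, 519 and 20307, they were 95, 95 and 2239. EAS against AS, with 3013, 3266 and 21878, had highest others of 111, 111 and 254. Among the 8 splits that, like the real one, part every same-day pair, the highest other counts of calls were 588 for SAL against End, 72 for EAS against AS and at most 3 in the other comparisons. In 100 regroupings of the 24 libraries, the real one included, 192 embryo, 31 endosperm, 85 EAS, 75 SAL and 642 pericarp-enriched genes were each reached under the same tissue name by 1, the real one (highest other 0). Under the AS name every regrouping reaches 0, so all 100 did, and the highest other was 200. Tissue names are interchangeable in a regrouping, and under any name 2 of the 100 reached the embryo, endosperm, EAS and SAL counts and 1 the pericarp count. The regrouping with 200 had drawn Emb replicates 1, 2, 3 and 4 together under the AS name, which points to the structure of the embryo libraries, and it was the only 1 besides the real grouping with any enriched gene. Regroupings that mix the tissues widen the spread in the same way, so they do not gauge the size of the sets.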

How the results depend on the processing

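The fits without the 3 libraries with deviating dates and without the shallowest library were chosen after the result was seen, and the planned gene lists were not run. Adding the replicate number as a block ended no microRNA call and moved no count by more than 1.5 times; the AS-high count stayed at 35 and the SAL-high count became 1300. RLE factors, upper quartile factors, legacy quasi-likelihood and both added exclusions also left every count they were run for within 1.5 times of its main value. Requiring 1 CPM in 12 libraries keeps 20172 of the 26543 features. It removes those of single tissues and also those shared by Emb and AS alone or by End and EAS alone. This filter gave 1101 higher and 1323 lower for Emb against End. It gave 1656 and 770 for Per against Emb, 1167 and 376 for Per against End, and 12 and 214 for AS against Emb. It gave 123 and 636 for EAS against End, 367 and 267 for SAL against End, and 1388 and 1913 for EAS against AS. Enriched sets became 7 in Emb, 8 in End, 23 in EAS, 3 in SAL and 107 in Per. Without a filter, with 35641 features tested, Per against End had 1309 lower and AS against Emb 57 higher, and enriched sets were 3 in AS, 58 in End and 115 in SAL; more features tested is part of that construction. DESeq2 gave 64 for AS against Emb higher, and the cause was not tested. Fitting only the compared tissues, with 4 libraries each and fewer features, gave 14 for AS against Emb higher, 825 for EAS against End lower and 808 for SAL against End higher. Leaving out each replicate in turn, the AS-high count ranged from 21 without Emb replicate 2 to 77 without Emb replicate 3, and no other count moved by more than 1.5 times. Of the scalings, upper quartile factors moved the median log2 fold change most, by -0.10 for EAS against End, and the fit to SAL and End alone moved it by -0.14. The higher share of 8-fold SAL against End calls, 71.2%, was 57.9% with the stricter filter and 61.3% in that fit. No microRNA locus or printed gene reversed in any other fit in which it was tested; they were not followed in the 2 added exclusions, and most were not in the stricter filter. Calls of microRNA loci lost significance in 74 cases when a replicate was left out, 6 by DESeq2, 4 with legacy quasi-likelihood, 3 without a filter and 2 with the compared tissues alone. The microRNA loci held 821 reads in SAL replicate 2 and at most 5767 in any library, so levels under 0.162 CPM rest on fewer than 3 reads in the shallowest library.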

Other observations

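Members of the same microRNA family peaked in different tissues, in pairs of loci chosen after their levels were seen. The log2 ratio of MIR156j to MIR156e reads, with 0.5 added to each count, was 9.0 ± 0.600 in EAS and -9.22 ± 0.738 in AS (SD, n = 4). The ratio of MIR159f to MIR159a, both of the GAMYB-targeting family, was 7.15 ± 0.778 in EAS and -3.62 ± 0.350 in Emb. MIR167g to MIR167h gave 10.10 ± 1.07 in End and 0.98 ± 0.242 in Per, and MIR171e to MIR171d gave 6.52 ± 1.30 in SAL and 0.48 ± 0.126 in Emb. MIR167g and MIR171e thus stayed above their relatives in both tissues, and MIR156e, compared in AS, had its highest mean in Emb (9.16 CPM). Loci and tissues were picked for their differing levels, so no test of these ratios is given.

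Pairs of tissues outside the 7 comparisons placed SAL between endosperm and pericarp. SAL and Per differed in 1845 features called 8-fold, 1207 of them higher in Per and 638 higher in SAL, near the 1803 between SAL and End and below the 4032 between SAL and EAS. Of those 4032, 3486 were higher in SAL. MIR396a was at 1.39 ± 0.214 CPM in SAL and 1.28 ± 0.234 in Per, MIR168b at 1.58 ± 0.339 and 2.03 ± 0.436, and MIR167e at 0.928 ± 0.135 and 1.42 ± 0.0919, whereas MIR171e was at 7.14 ± 1.39 and 0.515 ± 0.0787. Pericarp RNA in the SAL samples was not separated from likeness of the tissues in these values. SAL replicate 1, with the highest pericarp-marker share (18.8%), lay nearest to Per on the second principal component, and replicate 2, with the lowest (10.2%), lay farthest.

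The following tests were chosen after the levels per library had been seen. Within tissues, 1000 of the 26543 features differed between replicate numbers, which the labels tie to harvest days, at an edgeR adjusted p under 0.05. Only the real numbering, 1 of 100 permutations of the numbers within tissues, gave as many, and the highest other gave 157. Harvest day is a candidate explanation, although libraries made together would give the same picture and no label tells the difference. Of the 48 microRNA loci, MIR408b had such a difference (edgeR adjusted p = 0.0353, log2 fold of replicate 2 over replicate 1 of 0.98).

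MIR398a, MIR398b, MIR408b and MIR528a, precursors of microRNAs linked to copper proteins, had their highest summed level in replicate 2 in 4 of the 6 tissues. A shared harvest day may have raised them, but the permutation p of the largest mean deviation of a replicate number over the 6 tissues was 0.257, so the hypothesis was not borne out at this number of libraries and stays open. That test weighed the tissues equally, though summed levels were at most 0.359 CPM in EAS and 0.858 CPM in Per. In the fit to counts, replicate 2 was highest for each of these loci. The edgeR adjusted p was 0.0353 for MIR408b, 0.096 for MIR528a, 0.308 for MIR398a and 0.309 for MIR398b. Library depth was argued against as the cause in AS, where replicate 2 stood at 1.68 times the mean of the other 3 libraries while the largest AS library, after TMM scaling, was 1.02 times the smallest.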
